A study of Homo sapiens with 15 samples.

How the data were processed

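Values came from the deposited table, which the labels describe as a log ratio of treated over untreated RNA for 45220 probes on 15 arrays, with no missing values. The base was not stated by the authors and the unit was taken as log2; the deposited numbers spanned −4.09 to 4.83. Per the submitters' processing notes the ratios were computed with limma, with no version named, and the background correction and normalization were not given in the sources used here. Per the labels' protocols, cells were thawed 10 days before treatment, RNA was extracted with Trizol and RNeasy columns, and 700 ng was labelled. Signal intensities and raw scans were not used here. No array was left out, and no value column of the table went unused.

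The direction treated over untreated was taken from the sample labels and dyes. In replicate 3 the dyes were exchanged, so it was asked, by a rule fixed before the data were examined, whether its ratios had already been turned; the median correlation of replicate 3 with the mean of replicates 1 and 2 over all probes was 0.325, and its values were used as deposited. That correlation was −0.0895 at 2 h over all probes and 0.54 over genes alone. The orientation is least certain at 2 h.

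Probes were assigned to genes with the platform annotation: 31332 probes had 1 symbol, 93 had several and were left out, and 13795 had none, which may include control spots and were left out as well. Gene identifiers of 31291 probes were found in the reference gene table and took its symbols. The 18334 genes were each given the mean of their probes, with more than 1 probe for 7759. The 30 gene lists held 840 distinct genes, of which 781 were measured, and 25 genes were followed by name at every time.

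Each gene was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) with 5 time means and a dye term of opposite sign for treated RNA in Cy5 and in Cy3, leaving 9 residual degrees of freedom and a prior of 3.47. Because the exchanged dyes occur only in replicate 3, the dye term also absorbs what is peculiar to the third thawing. It passed for 3693 genes. The mean of 48 h and 72 h minus the mean of 2, 6 and 10 h was tested as a contrast. A moderated F test used 4 contrasts, each later time minus 2 h. P values were adjusted by Benjamini and Hochberg over all genes within each comparison, and a gene was called at an adjusted p under 0.05. Errors after ± are SEs from limma. Replicates were biological, because each came from a different thawing.

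Lists were tested with limma's camera on the same design, with the correlation between genes preset at 0.01 and, as an alternative, estimated for each list; p values were adjusted over the 30 lists of a comparison. Members were also adjusted over the list alone. How many lists camera calls without any change was counted on 100 simulated data sets, made by random mixing of the real residuals so that correlated genes stayed correlated. This was done for 72 h and for late minus early, and the draws for 72 h also served the list p values of the other times.

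Genes were named by a rule fixed before the data were examined: at each time the 8 highest and 8 lowest genes that passed with 1 sign on all 3 arrays, 6 of each for late minus early, up to 4 members of each list, and the genes followed by name. Uncharacterised loci were left out of that rule. The text names a part of these and prefers genes kept when single arrays are removed.

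Replicates of the same number were paired across times, as the labels describe. Residual correlations between arrays of the same number averaged 0.183, 0.153 and 0.525 for replicates 1, 2 and 3 before the dye term, and −0.0573, −0.0526 and −0.243 with it. The dye term makes each gene's replicate 3 residuals cancel over the 5 times, so their negative correlation is built in. Thawings were entered as a fixed block beside the dye term in an alternative fit, and as a random block in another, where limma's duplicateCorrelation gave −0.0542. The fixed block separated replicates 1 and 2 only, because the dye term already sets replicate 3 apart. The duplicateCorrelation value was likewise computed with the dye term in the model. None of these values shows that arrays of the same thawing are independent. A self-test drew random data without any change, with each gene's own residual SD and dye term, and added known changes to 200 genes at 48 h in each of 10 draws: 56.6% of changes of 0.3 on the log2 scale were recovered, 87.6% of 0.5 and 99.5% of 1.0, with 5.2% of calls false. For late minus early 11.9%, 47.2% and 89.1% were recovered, and by the F test 20.3%, 64.6% and 96.1%. In these draws genes were independent and each gene had 1 SD on all arrays. Only 200 genes changed, against 6942 called at 48 h in the real data. The recovered and false shares therefore need not hold for the real comparisons.

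Alternatives fixed before the data were examined were the fit without the dye term, both replicate blocks, each time alone, a test per probe, the median of a gene's probes, centring each array on its median, scaling arrays to the same spread, array weights, genes with a ratio on all arrays, robust eBayes, camera with an estimated correlation, and leaving out each array or each replicate at all times. Without replicate 3 the dye term cannot be fitted and was left out. The fits of each time alone also had no dye term. The counts of list members without single arrays and without the dye term were chosen after seeing the data. Python drew the figures.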

Results

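The series asked how valproic acid acts on blood cell formation, and its arrays profiled K562 cells, an erythroleukaemic line derived from a patient with chronic myeloid leukaemia. Cells were treated with 1 mM valproic acid, an anticonvulsant fatty acid that inhibits histone deacetylases, or left untreated, and RNA was taken after 2, 6, 10, 48 and 72 h. Treated and untreated RNA of the same time and culture was hybridised together on 2-colour expression arrays, with 3 arrays at each time and 15 in all. Per the labels, the 3 replicates at each time came from separate thawings of the line. Treated cells carried Cy5 in replicates 1 and 2 and Cy3 in replicate 3. The deposited values were log ratios of treated over untreated RNA for 45220 probes, which gave ratios for 18334 genes. The base of the logarithm was not stated and was taken as log2, so folds rest on that reading while the tests do not. Array medians lay between −0.00522 and 0.0169, and their SDs over probes between 0.211 and 0.432. Signal intensities were not used here, so no dim probes were removed, no expression level is given, and the number of arrays limits the precision. The median SE of a gene's ratio at a single time was 0.0602 on the log2 scale. It was the same at every time because each gene's spread was pooled over all 15 arrays. Array weights are lower for arrays that scatter more around the fitted ratios. They ran from 1.277 to 2.744 at 2 h and from 0.3919 to 0.7631 at 72 h. Errors and p values at 72 h may therefore be too small, and those at 2 h too large. Ratios of near-identical genes, such as HBG1 and HBG2, HBA1 and HBA2, the histones, the metallothioneins and the HLA genes, are uncertain because a probe can bind the RNA of several members.

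The response was broad from 6 h onward, with more genes higher than lower at every time. At 2 h 884 genes rose and 281 fell in treated cells, 6.35% of those tested. That number was not stable, since scaled arrays gave 3875 genes at 2 h and array weights 3253 (5247 and 6275 at 6 h). The counts were 3485 and 1771 at 6 h, 3310 and 2128 at 10 h, 4264 and 2678 at 48 h, and 4060 and 2499 at 72 h. Together these were 28.7%, 29.7%, 37.9% and 35.8% of the genes tested. Most changes were small: the median size among the genes that rose at 48 h was 0.39 on the log2 scale, and among those that fell 0.30. Large changes were nearly all increases, since 496 genes were at least 2-fold higher and 24 at least 2-fold lower at 48 h, and 88 were at least 4-fold higher. Neighbouring times shared many genes: 2635 rose at both 6 h and 10 h where independent lists would share 629, and 3258 rose at both 48 h and 72 h where independent lists would share 944. These times had no array in common but shared thawings and dye orientation. Each gene also had the same estimate of spread and of the dye term at every time. The excess therefore does not measure a shared effect alone. At all 5 times 472 genes were higher and 113 were lower. These counts cannot exceed the genes called at 2 h, which numbered only 398 without 2 h replicate 3.

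**Figure D1:**
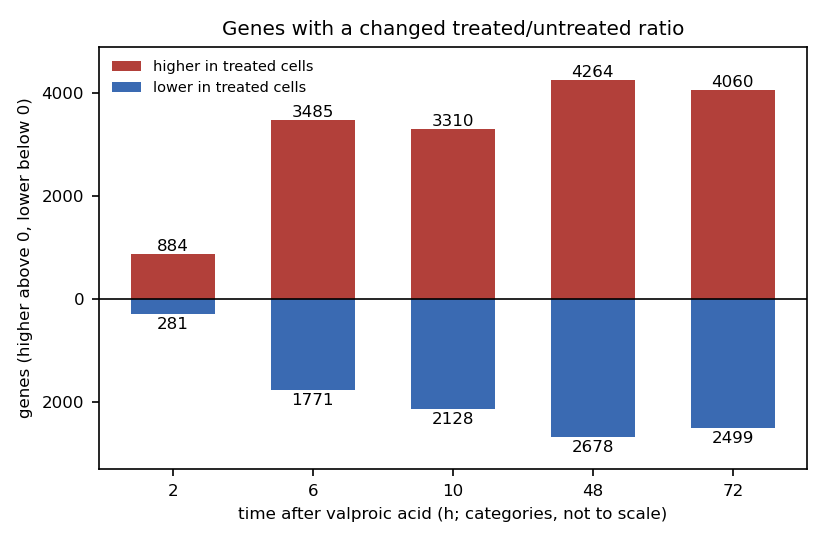
Number of genes (vertical axis) that passed limma's test at each time after treatment (horizontal axis, hours, categories not to scale), with genes higher in treated cells above 0 and genes lower below 0. The bars run from 884 higher and 281 lower genes at 2 h to 4264 and 2678 at 48 h, with a dip in higher genes from 3485 at 6 h to 3310 at 10 h.

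Gene groups were described with 30 lists fixed before the data were examined, as were the gene test and the rule for the genes named. Each list was tested against all other genes with limma's camera at a preset correlation between genes of 0.01. This called 9, 9, 7, 12 and 14 of the 30 lists at 2, 6, 10, 48 and 72 h. When the correlation was estimated for each list, camera called 0 lists at every time, with 1, 1, 2, 5 and 7 lists at an unadjusted p under 0.05. In 100 simulated data sets without any change at 72 h, the preset test still called a median of 5 lists and at most 12, so a list's call alone is weak evidence and the counts of its members carry the description. These counts have to be read beside the share of all genes that passed at the same time. A count near that share does not set a list apart. For each called list, and for some lists not called, the number of these 100 simulated data sets with a list p as low is given below. The median, the mean and the test of a list differed in sign in 29 of 180 list comparisons, and in each of these the list was not called.

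At 2 h the genes that rose most included HECA (1.25 ± 0.10, SE), GLRX, which encodes the thiol reductase glutaredoxin (1.24 ± 0.14), CDKN2D, an inhibitor of cyclin-dependent kinases (1.19 ± 0.14), MARCHF9, a membrane-bound ubiquitin ligase (1.19 ± 0.06), BTN2A2 (1.17 ± 0.11) and the ubiquitin protease gene USP35 (1.16 ± 0.12). Their limma adjusted p lay between 3.00e-06 and 0.000278, and each was higher on 3 of 3 arrays. MIR17HG, the host transcript of an oncogenic microRNA cluster, fell by 1.18 ± 0.11 (adjusted p = 5.19e-05) and MYC, a transcription factor that drives cell growth, by 0.92 ± 0.11 (adjusted p = 0.000315), both on 3 of 3 arrays. PLD6 and ZBTB3 were also lower, with log2 ratios of −0.79 and −0.70. Among 35 genes of the BCL2 family, caspases and death receptors, 5 were higher and 1 was lower (8 and 3 adjusted over the list alone), and the death receptor TNFRSF10B (0.71), the apoptosome component APAF1 (0.64) and the pore-forming BAK1 (0.59) were among those that rose. The list was not called (adjusted p = 0.138), and only 3 were higher without 2 h replicate 1, 2 or 3.

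Lists of growth-related, histone and lineage genes were called as lower at 2 h. Of 34 ribosome biogenesis genes, 3 fell and 1 rose (8 and 1 adjusted over the list alone). Without 2 h replicate 1 or 3, limma called 0 of them as lower, where 12 had been lower at an unadjusted p under 0.05 with all arrays. The list's median was −0.14 and its adjusted p 1.01e-06, or adjusted p = 0.496 with an estimated correlation. In limma 0 of 39 cytosolic ribosomal protein genes passed, with 2 lower at an unadjusted p under 0.05, yet the list was called as lower (median −0.10, adjusted p = 2.63e-06, and adjusted p = 0.496 with an estimated correlation). A small shift was also called for 46 replication-dependent histone genes (median −0.09, adjusted p = 4.83e-05), where 1 gene passed, 0 passed adjusted over the list alone, and 7 were lower at an unadjusted p under 0.05. It had adjusted p = 0.496 with an estimated correlation. Among 34 erythroid genes 2 were lower (2 adjusted over the list alone), namely NFE2, a transcription factor of erythroid and megakaryocytic cells (−0.58), and KLF1, the erythroid Krüppel-like factor (−0.44), whose call ended without 2 h replicate 1 (adjusted p = 0.0692) or 2 h replicate 3 (0.205). Only 1 erythroid gene was lower without 2 h replicate 1 or 3. The erythroid list was called as lower (adjusted p = 0.0136), and had adjusted p = 0.496 with an estimated correlation. Of 32 hematopoietic transcription factors 5 were lower and 1 higher (7 and 4 adjusted over the list alone), and the list was called as lower. Of these, 3 were lower without 2 h replicate 1, 1 without 2 h replicate 3 and 3 without the dye term. Tested as a list, these genes had adjusted p = 0.0136, and adjusted p = 0.466 with an estimated correlation.

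Induced lists at 2 h were small. Among 29 immediate early genes, which respond to stimuli within minutes, 6 rose and 1 fell (11 and 1 adjusted over the list alone). The adjusted p was 0.00586, or adjusted p = 0.496 with an estimated correlation. Without 2 h replicate 1, 2 or 3 the number of these that rose was 2, 3 and 0, where 12 had been higher at an unadjusted p under 0.05 with all arrays, and it was 3 without the dye term. Of 7 cyclin-dependent kinase inhibitor genes 3 rose (3 adjusted over the list alone; adjusted p = 0.0246, and 0.0550 without replicate 2 at all times), and so did 3 of 23 genes often induced by histone deacetylase inhibitors (4 adjusted over the list alone; adjusted p = 0.0313, 0.159 or 0.270 without replicate 2 or 3, and 0.0538 without the dye term). In both lists only 1 gene rose without 2 h replicate 1, 2 or 3. None of the 10 metallothionein genes passed in limma, 6 were higher at an unadjusted p under 0.05 and 6 passed adjusted over the list alone. That list had an adjusted p of 0.0172, which became 0.351 without replicate 2. These 3 lists each had adjusted p = 0.496 with an estimated correlation. Of the 100 simulated data sets without change, 38 had a list p as low as the real one at 2 h for metallothioneins, 37 for histone genes, 28 for cytosolic ribosomal proteins, 16 for erythroid genes and 15 for ribosome biogenesis. The number was 11 for genes often induced by histone deacetylase inhibitors, 8 for cyclin-dependent kinase inhibitors, and at most 3 for the 2 other called lists. The number of changed genes at 2 h was the least stable of all times: it was 526, 689 and 398 without 2 h replicate 1, 2 and 3, and 593 and 612 without replicate 1 and replicate 3 at all times.

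At 6 h the largest increases were in FBXL16, which encodes an F-box protein (2.90 ± 0.17, SE; adjusted p = 8.53e-07), MARCKS, a membrane and actin-binding substrate of protein kinase C (2.31 ± 0.23), SLC30A3, a zinc transporter (2.24 ± 0.17), ARHGEF40, a guanine nucleotide exchange factor (2.23 ± 0.14), CSRP2, a LIM domain protein (2.21 ± 0.14), and GLRX (2.18 ± 0.14). The largest decreases were in UBXN8 (−1.36 ± 0.15; adjusted p = 2.65e-05), PLD6 (−1.22 ± 0.10), the transcription factor gene TFAP2B (−1.22 ± 0.15), ARMC5 (−1.13 ± 0.12), RFESD (−1.10 ± 0.09) and COQ7, an enzyme of ubiquinone synthesis (−1.03 ± 0.07; adjusted p = 1.65e-06). Each had the same sign on 3 of 3 arrays, and limma's adjusted p was at most 7.00e-05. KLF1 was lower (−0.71 ± 0.09; adjusted p = 8.22e-05), as were the transferrin receptor gene TFRC (−0.55 ± 0.10; adjusted p = 0.00142) and GATA1, the principal erythroid GATA factor (−0.27 ± 0.05; adjusted p = 0.00181). CEBPA, a transcription factor of the granulocytic lineage, was higher (0.50 ± 0.08; adjusted p = 0.000522).

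Genes for making ribosomes were lower almost as a block at 6 h. Of 34 ribosome biogenesis genes 28 fell and the other 6 did not pass (30 lower adjusted over the list alone), including NOP16 (−0.95), UTP20 (−0.90), GRWD1 (−0.76) and NIP7 (−0.74). The median was −0.47 and the list's adjusted p 1.13e-16, or adjusted p = 0.400 with an estimated correlation. Metallothioneins, which bind zinc and copper, rose in 7 of 10 cases (8 adjusted over the list alone), with MT2A at 1.35, MT1F at 0.95 and MT1X at 0.90. The list test gave adjusted p = 0.000769, and adjusted p = 0.431 with an estimated correlation. Of the 23 genes often induced by histone deacetylase inhibitors 10 rose (12 adjusted over the list alone), among them GLRX, CDKN1A, which encodes the cell cycle inhibitor p21 (1.10), the actin-severing protein gene GSN (1.04) and ENO2 (1.03). Among 29 immediate early genes 14 rose and 1 fell (15 and 2 adjusted over the list alone), led by FOS (1.02), IER3 (1.01) and JUN (0.94). Of 33 genes of fatty acid oxidation and lipid droplets 16 rose and 1 fell (19 and 1 adjusted over the list alone), including ACSL1 (1.19), ANGPTL4 (1.12), CPT2 (0.69) and PLIN3 (0.65). These 3 lists each had an adjusted p of 0.000769 and adjusted p = 0.400 with an estimated correlation.

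Other lists were also called at 6 h. Of the 35 genes of cell death 14 rose and 2 fell (17 and 3 adjusted over the list alone), with BNIP3L (1.09) and BMF (0.95) in front. Of these, 9 rose without 6 h replicate 3, and the list's adjusted p of 0.0445 became 0.204 without replicate 3, 0.0589 without the dye term and adjusted p = 0.431 with an estimated correlation. Of 22 glycolytic genes 7 rose and 2 fell (8 and 2 adjusted over the list alone), with PFKM at 0.81, PFKP at 0.75 and the hexokinase gene HK2 at −0.60. The adjusted p of 0.0459 became 0.204 without replicate 3 and adjusted p = 0.400 with an estimated correlation. Of 34 erythroid genes 9 fell and 2 rose (10 and 2 adjusted over the list alone), and the list was called as lower, with 5 lower without 6 h replicate 3. Camera called this list with adjusted p = 0.0165, and adjusted p = 0.400 with an estimated correlation. Members that rose included the carbonic anhydrase gene CA2 (0.50). The histone list was called as lower (4 of 46 fell, 2 adjusted over the list alone), but this ended without replicate 3 (0.435), and 2 members were lower without 6 h replicate 2 or 3. As a group these genes had adjusted p = 0.0248, and adjusted p = 0.850 with an estimated correlation. A list p as low occurred in 61 of the 100 simulated data sets for histone genes at 6 h, 18 for erythroid genes, 14 for metallothioneins, and at most 2 for the 6 other called lists.

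FBXL16, MARCKS and CSRP2 were again among the genes that rose most at 10 h. FBXL16 reached 3.05 ± 0.17 (SE), MARCKS 3.03 ± 0.23, CSRP2 2.84 ± 0.14, REEP2, a protein that shapes the endoplasmic reticulum, 2.84 ± 0.12, AIF1L, an actin-bundling protein, 2.73 ± 0.15, and TMEM132A 2.45 ± 0.11, each on 3 of 3 arrays with a limma adjusted p of at most 1.44e-06. The lowest were TFAP2B (−1.14 ± 0.15), the tRNA dihydrouridine synthase gene DUS3L (−1.10 ± 0.09; adjusted p = 4.00e-06), PLD6 (−1.07 ± 0.10), ARMC5 (−1.05 ± 0.12), UBXN8 (−1.05 ± 0.15) and ADI1, an enzyme of methionine salvage (−1.03 ± 0.08). KIT, the stem cell factor receptor, was higher (0.99 ± 0.16; adjusted p = 0.000478), as were CEBPA (0.67 ± 0.08; adjusted p = 5.33e-05) and the apoptosis inhibitor gene BCL2 (0.34 ± 0.06; adjusted p = 0.000940). KLF1 (−0.72 ± 0.09; adjusted p = 6.11e-05) and TFRC (−0.71 ± 0.10; adjusted p = 0.000224) stayed lower.

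Of the 34 ribosome biogenesis genes 31 were lower at 10 h and the other 3 did not pass (31 adjusted over the list alone), with UTP20 at −0.82, MYBBP1A at −0.76 and LYAR at −0.75 (median −0.49, adjusted p = 1.06e-17, and adjusted p = 0.404 with an estimated correlation). Metallothioneins rose in 8 of 10 cases (8 adjusted over the list alone), up to 2.00 for MT2A (adjusted p = 2.59e-06). Among genes often induced by histone deacetylase inhibitors 12 of 23 rose (14 adjusted over the list alone), with GLRX at 2.06 and GSN at 1.36 (adjusted p = 5.61e-05). Genes that present antigen to T cells were called for the first time at 10 h: 8 of 18 rose and 1 fell (8 and 1 adjusted over the list alone), namely the peptide transporter TAP1 (1.91) and the class I genes HLA-C (1.72), HLA-B (1.32) and HLA-E (1.26) among others (adjusted p = 0.0128). Fatty acid oxidation and lipid droplet genes rose in 15 of 33 cases and fell in 1 (16 and 1 adjusted over the list alone; adjusted p = 0.00108), with ANGPTL4 at 1.09 and ACAA2 at 0.73. Of 34 erythroid genes 10 fell and 2 rose (11 and 3 adjusted over the list alone; adjusted p = 0.0221), and 4 were lower without 10 h replicate 3. Of the 35 cell death genes 14 rose and 3 fell (15 and 4 adjusted over the list alone), including BNIP3L (1.01), BMF (0.98) and BAD (0.74). This call (adjusted p = 0.0433) ended without replicate 3 (0.172) and without the dye term (0.0640). Each of these 6 lists after the ribosome biogenesis genes had adjusted p = 0.407 with an estimated correlation. In the simulated data sets a list p as low as at 10 h occurred 18 times of 100 for erythroid genes, and at most 3 times for the 6 other called lists. The number of changed genes at 10 h was 3389 without 10 h replicate 3.

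At 48 h the largest increases of the series were reached. TMSB15A, a thymosin that binds actin monomers, was higher by 4.22 ± 0.10 (SE; adjusted p = 6.23e-11), MARCKS by 4.16 ± 0.23, the phospholipase and acyltransferase gene PLAAT3 by 3.89 ± 0.10, AIF1L by 3.85 ± 0.15, CRYM, which binds thyroid hormone, by 3.79 ± 0.20, the growth factor-binding IGFBP2 by 3.70 ± 0.14 and S100A10, a partner of annexins, by 3.61 ± 0.09. Decreases were smaller, with PLD6 at −1.38 ± 0.10 (adjusted p = 3.60e-07), the phospholipase C gene PLCD1 at −1.35 ± 0.12, asparagine synthetase, ASNS, at −1.24 ± 0.12, ACTL8 at −1.24 ± 0.13, lymphotoxin beta, LTB, at −1.23 ± 0.14 and the desmosomal plakophilin PKP3 at −1.19 ± 0.09. Each of these had the same sign on 3 of 3 arrays and a limma adjusted p of at most 1.92e-05. KIT rose to 2.03 ± 0.16 (adjusted p = 7.69e-07) and MYB, a transcription factor of immature blood cells, to 0.77 ± 0.10 (adjusted p = 3.52e-05). The integrin gene ITGAM, a surface marker of myelo-monocytic cells, was higher (0.93 ± 0.11; adjusted p = 2.38e-05), while KLF1 (−0.84 ± 0.09; adjusted p = 9.51e-06) and the fetal globin gene HBG2 (−0.81 ± 0.14; adjusted p = 0.000599) were lower.

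Lists of metal binding, antigen presentation and the genes often induced by histone deacetylase inhibitors were called as higher at 48 h. Metallothioneins rose in 7 of 10 cases (7 adjusted over the list alone) with MT2A at 3.21 and MT1X at 2.29 (median 1.88, adjusted p = 2.49e-06, and adjusted p = 0.279 with an estimated correlation). Antigen presentation genes rose in 10 of 18 cases and fell in 1 (10 and 1 adjusted over the list alone), with HLA-C at 2.99, HLA-B at 2.76, TAP1 at 2.36 and HLA-F at 1.92. Their list was called with adjusted p = 0.000271, and adjusted p = 0.215 with an estimated correlation. Of 23 genes often induced by histone deacetylase inhibitors 15 rose (16 higher and 1 lower adjusted over the list alone), including DHRS2 (3.05), GSN (1.98) and CRIP1 (1.93). Tested as a list, these genes had adjusted p = 3.36e-06, and adjusted p = 0.215 with an estimated correlation. Of the 7 cyclin-dependent kinase inhibitors 4 rose (5 adjusted over the list alone), with CDKN2D at 2.08, CDKN1A at 1.53, CDKN3 at 0.63 and CDKN1C at 0.50. The list test gave adjusted p = 0.0165, and adjusted p = 0.279 with an estimated correlation. Ribosome biogenesis genes stayed lower in 30 of 34 cases (31 adjusted over the list alone; median −0.47, adjusted p = 1.47e-14, and adjusted p = 0.215 with an estimated correlation), led by MYBBP1A (−0.97), LYAR (−0.82) and NOP2 (−0.75).

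Other lists called at 48 h held genes of signalling, lipid metabolism and other tissues. Immediate early genes rose in 15 of 29 cases and fell in 3 (17 and 3 adjusted over the list alone), with FOS at 1.48 and IER3 at 1.29. Camera called this list with adjusted p = 0.00793, and adjusted p = 0.350 with an estimated correlation. Fatty acid oxidation and lipid droplet genes rose in 17 of 33 cases and fell in 2 (17 and 2 adjusted over the list alone). As a group these genes had adjusted p = 0.00793, and adjusted p = 0.356 with an estimated correlation. Cholesterol synthesis genes rose in 10 of 20 cases and fell in 1 (10 and 1 adjusted over the list alone), with TM7SF2 at 1.07 and the squalene epoxidase SQLE at 1.04. The adjusted p of 0.0161 became 0.146 without replicate 3 and adjusted p = 0.260 with an estimated correlation. Surface antigens used in blood cell phenotyping rose in 12 of 26 cases and fell in 1 (12 and 1 adjusted over the list alone), with KIT in front, the tetraspanin CD9 at 1.70 and the hyaluronan receptor CD44 at 1.03. Their list was called with adjusted p = 0.0191, and adjusted p = 0.260 with an estimated correlation. Neuronal genes rose in 15 of 39 cases and fell in 2 (15 and 2 adjusted over the list alone), including SCG3 (1.93), UCHL1 (1.69) and GAD1 (1.51). The adjusted p of 0.0237 became 0.122 without replicate 2 and adjusted p = 0.363 with an estimated correlation. Of 46 replication-dependent histone genes 10 fell and 4 rose (9 and 4 adjusted over the list alone), and 5 fell without 48 h replicate 2. Tested as a list, these genes had adjusted p = 0.0161, and adjusted p = 0.643 with an estimated correlation. Mitotic genes were lower in 7 of 34 cases and higher in 2 (7 and 2 adjusted over the list alone), with the cyclin CCNA2 at −0.71. Only 3, 4 and 4 were lower without 48 h replicate 1, 2 and 3. The mitotic call at 48 h (adjusted p = 0.0477) ended with the thawing as a replicate block (adjusted p = 0.0521), without replicate 1, 2 or 3 (0.0776, 0.0698 and 0.176), after centring each array on its median (0.0621) and without the dye term (0.0575), and it had adjusted p = 0.676 with an estimated correlation. Simulated data sets with a list p as low as at 48 h numbered 59 of 100 for histone genes, 56 for mitotic genes, 6 for cyclin-dependent kinase inhibitors, 5 for fatty acid oxidation and lipid droplets, and at most 3 for the 8 other called lists.

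At 72 h the leading genes were mostly those of 48 h. CRYM was higher by 4.10 ± 0.20 (SE; adjusted p = 1.69e-08), PLAAT3 by 3.89 ± 0.10, TMSB15A by 3.86 ± 0.10, S100A10 by 3.81 ± 0.09, AIF1L by 3.36 ± 0.15 and the extracellular matrix gene EMILIN2 by 3.05 ± 0.15. The calcium-binding S100P fell by 2.14 ± 0.36 (adjusted p = 0.000474), LTB by 1.40 ± 0.14, TNFRSF8, which encodes a receptor of the tumour necrosis factor family, by 1.28 ± 0.12, and TERT, the catalytic subunit of telomerase, by 1.20 ± 0.14 (adjusted p = 2.20e-05). All of these had the same sign on 3 of 3 arrays. TFRC was now higher (0.62 ± 0.10; adjusted p = 0.000404), as were the erythropoietin receptor EPOR (0.54 ± 0.06; adjusted p = 2.99e-05) and the survival gene BCL2L1 (0.43 ± 0.04; adjusted p = 7.77e-06). MYC fell by 0.51 ± 0.11 (adjusted p = 0.00340).

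Of 34 mitotic genes 24 were lower at 72 h and the other 10 did not pass (25 lower adjusted over the list alone), including CCNA2 (−0.90), the kinesin KIF2C (−0.65) and the kinase PLK1 (−0.58; list median −0.37, adjusted p = 2.92e-10, and adjusted p = 0.327 with an estimated correlation). Only 13 were lower without 72 h replicate 3. Genes of DNA replication and entry into S phase fell in 14 of 45 cases and rose in 4 (16 and 5 adjusted over the list alone), with the licensing factor CDT1 at −0.69, CCND3 at 0.77 and CCND1 at 0.70. The number that fell was 25 without 72 h replicate 2 and 2 without 72 h replicate 3, where 7 were higher, and the list's adjusted p of 0.00306 became 0.306 without replicate 3 and adjusted p = 0.474 with an estimated correlation. In contrast 15 of 46 replication-dependent histone genes rose (15 adjusted over the list alone), for instance H4C11 (0.58) and H1-3 (0.65). The count was 27 without 72 h replicate 1 and 11 without 72 h replicate 2. The histone call (adjusted p = 0.0167) ended without replicate 2 (0.977), and it had adjusted p = 0.558 with an estimated correlation. Of 7 cyclin-dependent kinase inhibitors 4 rose (4 adjusted over the list alone), among them CDKN2D (1.92) and CDKN1A (1.64), and 2 rose without 72 h replicate 1. The list test gave adjusted p = 0.0330, and adjusted p = 0.311 with an estimated correlation. Ribosome biogenesis genes were lower in 26 of 34 cases (27 adjusted over the list alone; median −0.44, adjusted p = 1.13e-11, and adjusted p = 0.148 with an estimated correlation). Of 32 genes of endoplasmic reticulum stress and amino acid supply 13 fell and 3 rose (15 and 4 adjusted over the list alone), including ASNS (−0.68), XBP1 (−0.74) and SLC7A5 (−0.65). In this list 7 rose without 72 h replicate 2, and the list's adjusted p of 0.000877 became 0.0994 without replicate 2 and adjusted p = 0.473 with an estimated correlation.

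Other lists were called as higher at 72 h. Genes often induced by histone deacetylase inhibitors rose in 17 of 23 cases (18 adjusted over the list alone; median 0.57, adjusted p = 2.89e-09, and adjusted p = 0.112 with an estimated correlation), with DHRS2 at 2.51 and CRIP1 at 1.82. Immediate early genes rose in 16 of 29 cases and fell in 1 (18 and 1 adjusted over the list alone), with FOS at 2.11 and ZFP36 at 1.11. Camera called this list with adjusted p = 1.19e-05, and adjusted p = 0.134 with an estimated correlation. Cholesterol synthesis genes rose in 14 of 20 cases and fell in 1 (14 and 2 adjusted over the list alone), including STARD4 (1.00) and INSIG1 (0.95). As a group these genes had adjusted p = 0.000552, and adjusted p = 0.112 with an estimated correlation. Glycolytic genes rose in 14 of 22 cases (14 adjusted over the list alone), led by ENO2 (1.69) and the glucose transporter SLC2A1 (1.06). Their list was called with adjusted p = 0.00264, and adjusted p = 0.119 with an estimated correlation. Antigen presentation genes rose in 10 of 18 cases and fell in 1 (10 and 2 adjusted over the list alone), with the immunoproteasome subunit PSMB9 at 1.95. Tested as a list, these genes had adjusted p = 0.000877, and adjusted p = 0.134 with an estimated correlation. Surface antigens rose in 12 of 26 cases and fell in 1 (13 and 1 adjusted over the list alone). The list test gave adjusted p = 0.000877, and adjusted p = 0.112 with an estimated correlation. Neuronal genes rose in 16 of 39 cases and fell in 1 (16 and 1 adjusted over the list alone; adjusted p = 0.00156, and adjusted p = 0.190 with an estimated correlation), and metallothioneins rose in 8 of 10 (8 adjusted over the list alone; adjusted p = 5.36e-07, and adjusted p = 0.190 with an estimated correlation). Of the 100 simulated data sets, 63 had a list p as low as at 72 h for histone genes, 38 for DNA replication, 26 for endoplasmic reticulum stress and amino acid supply, 12 for mitotic genes, 11 for cyclin-dependent kinase inhibitors, and at most 1 for the 9 other called lists. The number of changed genes at 72 h was 4213 without 72 h replicate 3 and 4309 without replicate 3 at all times.

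**Figure D2:**
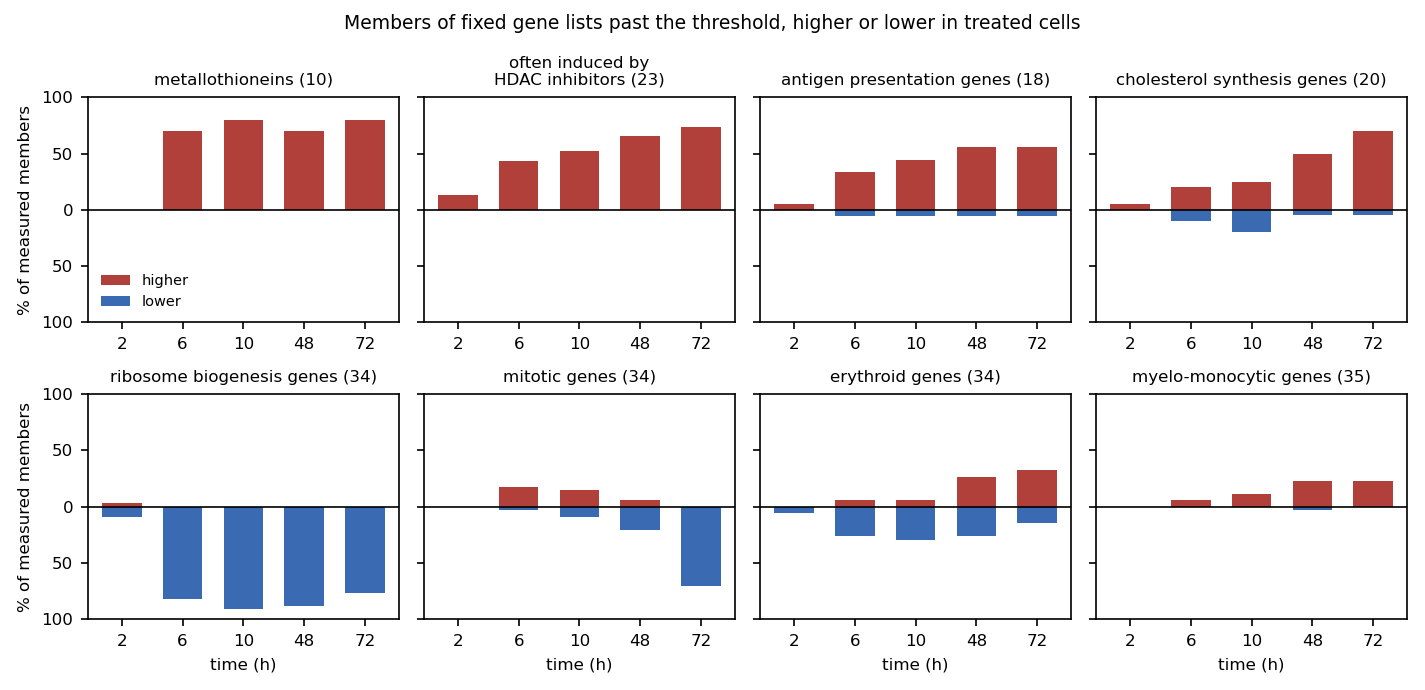
Percentage of the measured members of 8 gene lists (vertical axis) that were higher or lower in treated cells in limma's test at each time (horizontal axis, hours, categories not to scale). Ribosome biogenesis genes are almost all lower from 6 h on (28, 31, 30 and 26 of 34), mitotic genes are lower mainly at 72 h (24 of 34), and metallothioneins are higher from 6 h on (7, 8, 7 and 8 of 10).

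Lineage lists were followed at 48 h and 72 h, when 37.9% and 35.8% of all genes tested passed. Counts near or below these shares do not set a lineage apart. Of 34 erythroid genes 9 were higher and 9 lower at 48 h (9 and 11 adjusted over the list alone), and 11 were higher and 5 lower at 72 h (13 and 6 adjusted over the list alone). Neither list test passed (adjusted p = 0.210 and 0.279), and the 72 h median of 0.02 turned negative when each array was centred on its median. The erythroid genes lower at 72 h numbered 3 without 72 h replicate 1 and 2 without 72 h replicate 3. Adult globin HBB was lower at 48 h (−1.07 ± 0.15; adjusted p = 0.000116), HBD (0.73 ± 0.14; adjusted p = 0.00126, and 0.0532 without replicate 3 at all times) and the Rh antigen gene RHCE (1.12 ± 0.10; adjusted p = 3.52e-06) were higher at 72 h, and CA2 rose at 48 h (0.96) and 72 h (0.81). Of 35 myelo-monocytic genes 8 rose at 72 h (8 adjusted over the list alone; 5 without 72 h replicate 3), led by lysozyme, LYZ (1.76 ± 0.08; adjusted p = 7.21e-09), and ITGAM (0.82 ± 0.11; adjusted p = 7.43e-05), and the list was not called (adjusted p = 0.212). Of 22 megakaryocytic genes 6 rose and 1 fell at 72 h (5 and 1 adjusted over the list alone; adjusted p = 0.212 for the list), with CD9 at 1.30 ± 0.11. Without 72 h replicate 3, limma called 4 of these as higher and 0 as lower, where with all arrays 9 were higher and 1 lower at an unadjusted p under 0.05. Lymphoid genes rose in 4 of 27 cases and fell in 1 (3 and 0 adjusted over the list alone; adjusted p = 0.955 for the list), with the T cell receptor component CD3D at 1.57 ± 0.12. At an unadjusted p under 0.05, 4 were higher and 1 lower, and without 72 h replicate 3 limma called 0 as lower. Of 22 fibroblast and epithelial genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.319 for the list), with the collagen COL1A1 at 1.09 ± 0.06, the keratins KRT8 at 0.80 ± 0.08 and KRT18 at 0.73 ± 0.05, and the adhesion molecule EPCAM at −1.05 ± 0.07. A list p as low as at 72 h occurred in 1 of the 100 simulated data sets for megakaryocytic genes. It occurred in 58 for erythroid, 23 for myelo-monocytic, 95 for lymphoid, and 35 for fibroblast and epithelial genes.

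The regulators and antigens followed at every time differed in course. KLF1 was lower from 6 h to 72 h, and GATA1 was lower at 6 h with weak or no calls at other times. GATA1 at 10 h (−0.16, adjusted p = 0.0344, the same sign on 2 of 3 arrays) lost its call without 10 h replicate 1, 2 or 3 (0.177, 0.112 and 0.0561), and at 48 h (−0.16, adjusted p = 0.0300) without 48 h replicate 2 or 3 (0.204 and 0.138). GATA1 at 2 h (−0.18) passed only with the thawing as a replicate block (adjusted p = 0.0401 against 0.0648), as did HBG2 at 6 h (−0.40; adjusted p = 0.0377 against 0.0541). MYB was lower at 2 h (−0.49 ± 0.10; adjusted p = 0.00759), a call that ended without 2 h replicate 3 (0.148), and higher at 72 h (0.46 ± 0.10; adjusted p = 0.00200). CEBPA at 72 h (0.29, adjusted p = 0.0128) lost its call without 72 h replicate 1 (0.130), and without replicate 3 at all times (0.205). Embryonic HBZ was lower at 72 h (−0.90 ± 0.27; adjusted p = 0.0198), but not without 72 h replicate 3 (0.456), and fetal HBG1 at 48 h (0.22; adjusted p = 0.0467) lost its call without 48 h replicate 1, 2 or 3 (0.304, 0.0523 and 0.112) and with the replicate block (0.0579). The integrin genes ITGA2B at 48 h (0.25; adjusted p = 0.00488, and 0.153 without 48 h replicate 3) and ITGB3 at 72 h (0.10; adjusted p = 0.0457, 0.219, 0.0730 and 0.116 without 72 h replicate 1, 2 and 3, and 0.0512 with the replicate block) had small ratios. HDAC1 was higher at 72 h (0.41 ± 0.07; adjusted p = 0.000423, and 0.0631 without replicate 3 at all times), while HDAC2 passed at 48 h (0.36; adjusted p = 0.0370) but not without 48 h replicate 1, 2 or 3 (0.224, 0.0981 and 0.0505). At no time did SPI1, GATA2, CD14, CD34, ALAS2 or HBA1 pass. Their log2 ratios at 72 h were 0.05, 0.05, −0.01, 0.02, −0.39 and 0.21.

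**Figure D3:**
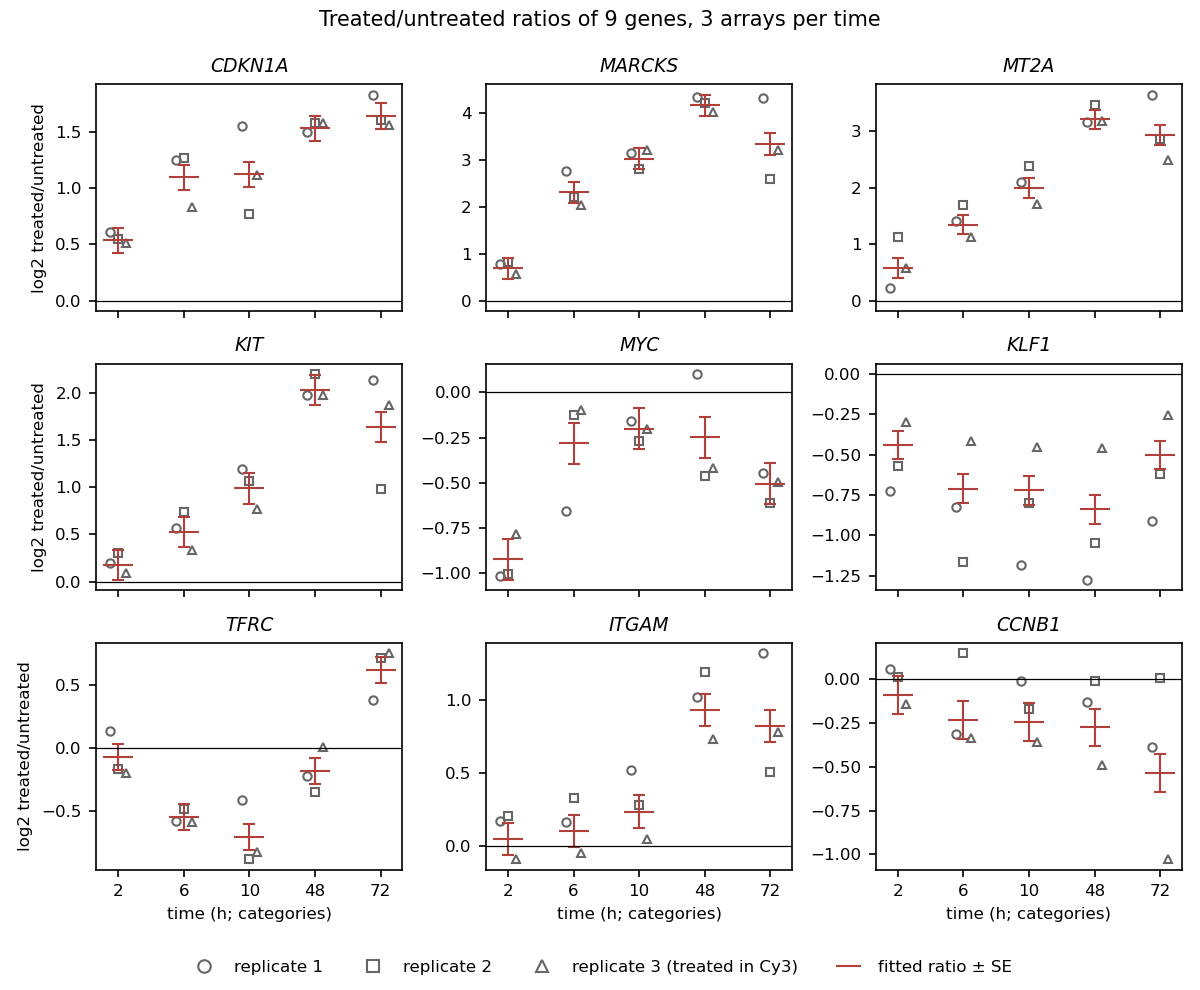
Log2 ratio of treated over untreated cells (vertical axis) at each time (horizontal axis, hours, categories not to scale) for 9 genes, with a symbol for each replicate array and the fitted ratio ± SE in red. CDKN1A, MARCKS, MT2A and KIT climb to 48 h, KLF1 stays below 0, TFRC crosses from −0.71 at 10 h to 0.62 at 72 h, and CCNB1 is lowest at 72 h (−0.53), where replicates 1, 2 and 3 had −0.39, 0.01 and −1.03.

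Metabolic and housekeeping lists that were not called held genes that changed at 48 h, when 37.9% of all genes tested passed. Where a list's share is near this, its changes do not set it apart. Of 22 genes of heme synthesis and iron handling, 7 rose and 7 fell (7 and 7 adjusted over the list alone; adjusted p = 0.348 for the list), with the biliverdin reductase BLVRA at 1.49 ± 0.11 and the mitochondrial glycine carrier SLC25A38 at −0.58 ± 0.05. Without 48 h replicate 3 the number that rose was 4, and without 48 h replicate 1 the number that fell was 4. Of 17 heat shock genes 2 rose and 6 fell (2 and 6 adjusted over the list alone; adjusted p = 0.0903 for the list), with the cochaperone DNAJA1 at −0.58 ± 0.07. Of 27 oxidative stress genes 5 rose and 9 fell (5 and 10 adjusted over the list alone; adjusted p = 0.204 for the list; 2 higher without 48 h replicate 1), with KEAP1 at −0.82 ± 0.11 and NQO1 at −0.48 ± 0.08. Mitochondrial respiratory chain genes rose in 4 of 28 cases and fell in 7 (4 and 7 adjusted over the list alone; adjusted p = 0.181 for the list), with cytochrome c1, CYC1, at −0.48 ± 0.07. Only 4 and 3 were lower without 48 h replicate 1 and 3, and 2 higher without 48 h replicate 3. Of 39 cytosolic ribosomal protein genes 17 rose and 4 fell (18 and 4 adjusted over the list alone; adjusted p = 0.0918 for the list), but 3 rose without 48 h replicate 1, 2 without 48 h replicate 3 and 3 without the dye term. RPL4 was lower (−0.39 ± 0.06). Interferon-stimulated genes rose in 11 of 27 cases and fell in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.109 for the list), with ISG20 at 0.75 ± 0.08 and RSAD2 at 0.76 ± 0.12. Of 27 histone deacetylases and acetyltransferases, 5 rose and 8 fell (5 and 10 adjusted over the list alone; adjusted p = 0.0779 for the list), with the acetyltransferases KAT2A at −0.71 ± 0.08 and KAT5 at −0.49 ± 0.08. Only 3, 2 and 1 rose without 48 h replicate 1, 2 and 3, and 3 without the dye term. A list p as low occurred in 0 of the 100 simulated data sets for the deacetylases and acetyltransferases, and in 21 or more for the other lists of this paragraph. Of 16 histone variant and polyadenylated histone genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.900 for the list), with the replacement histone H2AJ at −0.29 ± 0.06.

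The late response, the mean of 48 h and 72 h, was set against the early response, the mean of 2, 6 and 10 h, in the same model. CRYM (3.16 ± 0.18, SE; adjusted p = 1.55e-07), TMSB15A (2.97 ± 0.09), IGFBP2 (2.65 ± 0.13), PLAAT3 (2.55 ± 0.09), DHRS2 (2.47 ± 0.15) and the metalloproteinase inhibitor TIMP2 (2.29 ± 0.13) gained most. The differences were lowest for PLCD1 (−1.18 ± 0.10; adjusted p = 4.79e-06), the serine synthesis enzyme PSAT1 (−1.04 ± 0.08), the neuropeptide gene GAL (−1.01 ± 0.08) and TRIB3 (−0.99 ± 0.11), apart from S100P (−1.31 ± 0.33; adjusted p = 0.0105), which did not pass without replicate 2 (0.0901) or replicate 3 (0.148). KIT (1.27 ± 0.14; adjusted p = 3.80e-05), MYB (0.81 ± 0.09; adjusted p = 2.23e-05), ITGAM (0.75 ± 0.10; adjusted p = 0.000136), CDKN1A (0.67 ± 0.10; adjusted p = 0.000351) and TFRC (0.66 ± 0.09; adjusted p = 0.000212) were higher late, whereas KLF1 (−0.05, adjusted p = 0.741) and MYC (0.09, adjusted p = 0.591) did not pass. GATA1 at late minus early (0.13) passed only with the replicate block (adjusted p = 0.0475 against 0.0725). In all 4755 genes differed, 25.9% of those tested, 2732 with a higher and 2023 with a lower late ratio. Without replicate 3 the number was 1998.

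Several lists were called for late minus early. Mitotic genes were lower late in 19 of 34 cases (21 adjusted over the list alone), with CDC25C at −0.61 and CENPE at −0.48. Camera called this list with adjusted p = 8.18e-09, and adjusted p = 0.351 with an estimated correlation. Some mitotic genes were higher at the early times: 6 rose and 1 fell at 6 h (5 and 1 adjusted over the list alone; adjusted p = 0.244 for the list), and 5 rose and 3 fell at 10 h (5 and 3 adjusted over the list alone; adjusted p = 0.987 for the list). The number that rose was 10, 4 and 3 without 6 h replicate 1, 2 and 3, and 3, 5 and 2 without 10 h replicate 1, 2 and 3, where 2, 1 and 1 fell. Genes of endoplasmic reticulum stress and amino acid supply were lower late in 14 of 32 cases and higher in 1 (14 and 2 adjusted over the list alone). As a group these genes had adjusted p = 9.34e-05, and adjusted p = 0.434 with an estimated correlation. Ribosome biogenesis genes were lower in 13 of 34 cases and higher in 2 (15 and 3 adjusted over the list alone; adjusted p = 0.0282, 0.0735 and 0.0506 without replicate 1 and 3, and adjusted p = 0.596 with an estimated correlation), and DNA replication genes in 11 of 45 cases with 3 higher (13 and 4 adjusted over the list alone; adjusted p = 0.0331, 0.578 without replicate 3, and adjusted p = 0.667 with an estimated correlation). The ribosome biogenesis medians were −0.14, −0.47, −0.49, −0.47 and −0.44 at 2, 6, 10, 48 and 72 h. By its median this list was lower late than at 2 h only, and not lower than at 6 h or 10 h. Metallothioneins were higher late in 7 of 10 cases (8 adjusted over the list alone; adjusted p = 5.24e-07, and adjusted p = 0.214 with an estimated correlation), and genes often induced by histone deacetylase inhibitors in 13 of 23 with 1 lower (14 and 1 adjusted over the list alone; adjusted p = 3.75e-06, and adjusted p = 0.149 with an estimated correlation), CRIP1 (1.32) and the secreted chaperone CLU (1.01) among them. Antigen presentation genes (10 of 18 higher, 1 lower, and 10 and 1 adjusted over the list alone) and cholesterol synthesis genes (13 of 20 higher, 1 lower, and 13 and 1 adjusted over the list alone), among them HMGCS1 (0.69), each had an adjusted p of 7.16e-05 and adjusted p = 0.117 with an estimated correlation.

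Other lists were examined for late minus early as well. Erythroid genes were higher late in 12 of 34 cases and lower in 3 (14 and 5 adjusted over the list alone), with RHCE at 0.99, the Rh-associated glycoprotein RHAG at 0.68 and NFE2 at 0.62. The adjusted p of 0.0331 became 0.135 without replicate 3 and adjusted p = 0.351 with an estimated correlation. The erythroid medians were −0.02, −0.05, −0.08, −0.13 and 0.02 at 2, 6, 10, 48 and 72 h. By its median the erythroid list was higher than at the early times at 72 h only, and lower than these at 48 h. Hematopoietic transcription factors were higher in 10 of 32 cases and lower in 1 (10 and 1 adjusted over the list alone). The adjusted p of 0.0486 became 0.138 without replicate 1, 0.0623 without the dye term and adjusted p = 0.214 with an estimated correlation. Surface antigens were higher in 12 of 26 cases and lower in 1 (12 and 2 adjusted over the list alone), with the complement inhibitor CD59 at 0.57. Their list was called with adjusted p = 0.000772, and adjusted p = 0.117 with an estimated correlation. Neuronal genes were higher in 14 of 39 cases (14 higher and 2 lower adjusted over the list alone). Tested as a list, these genes had adjusted p = 0.000363, and adjusted p = 0.212 with an estimated correlation. Immediate early genes were higher in 10 of 29 cases (13 adjusted over the list alone), with FOS at 1.28 and JUND at 0.75. The list test gave adjusted p = 0.00502, and adjusted p = 0.346 with an estimated correlation. Replication-dependent histone genes were higher in 10 of 46 cases and lower in 1 (10 and 1 adjusted over the list alone). The adjusted p of 0.0364 became 0.349 without replicate 2, 0.0683 without replicate 3 and adjusted p = 0.682 with an estimated correlation. The histone medians were −0.09, −0.07, −0.03, −0.19 and 0.25 at 2, 6, 10, 48 and 72 h. By its median the histone list was higher than at the early times at 72 h only, and lower than these at 48 h. Myelo-monocytic genes were higher in 6 of 35 cases and lower in 1 (6 and 1 adjusted over the list alone), led by LYZ (1.67), but the list was not called (adjusted p = 0.130). Simulated data sets with a list p as low for late minus early numbered 70 of 100 for histone genes, 60 for DNA replication, 45 for ribosome biogenesis and 29 for erythroid genes. They numbered 17 for endoplasmic reticulum stress and amino acid supply, 12 for mitotic genes, 5 for immediate early genes, and at most 1 for the 7 other called lists. The megakaryocytic list was not called, yet 0 of the 100 had a list p as low. Of its 22 genes 8 were higher late and 1 lower at an unadjusted p under 0.05 in limma.

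A moderated F test asked which genes differed in ratio among the 5 times, whatever the course. It passed for 4277 genes, 23.3% of those tested, while 10161 genes passed at one time or more. From 6 h to 72 h 2587 genes passed at all 4 times in one direction, 1843 higher and 744 lower. Changes of direction between 6 h and 72 h were fewer: 128 genes went from higher to lower and 81 from lower to higher. The number of genes passing the F test was 2389 without replicate 2 and 920 without replicate 3. The fit without replicate 3 also lacks the dye term, and leaving out that term alone gave 2838 genes.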

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

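The genes in this paragraph were singled out because their response turned between 6 h and 72 h, and they were chosen after their values were seen. Tests of explanations in this part were also chosen after seeing the result, and some were reworded or divided after a first run; the exchanges and shuffles of labels were planned before. Late minus early passed for 128 genes higher at 6 h and lower at 72 h, and for 78 genes lower at 6 h and higher at 72 h. The late minus early difference was 2.204 for the chemokine gene CCL2, 1.713 for IL18RAP, 1.628 for TUBAL3, 1.16 for the glucose transporter SLC2A1 and 0.6606 for TFRC. It was −1.042 for PSAT1, −0.978 for CTH, −0.9184 for KDF1 and −0.8955 for NAT8L. CCL2 ran from −0.63 at 2 h to 2.08 at 72 h, and CTH, an enzyme of cysteine synthesis, from 0.65 at 6 h to −0.85 at 72 h.

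Replicate 3 stood apart from replicates 1 and 2. A dye bias, or a difference of replicate 3's thawing shared by all times, could account for this, since the difference between replicates 1 and 2 and replicate 3 correlated between times with a mean of 0.5249. A thawing whose difference was wholly in proportion to the drug response was argued against. The shared difference grew 1.334-fold from 2 h to 48 h (bootstrap SE 0.0186) while the SD of the response grew 2.547-fold. The bootstrap resampled genes, which are correlated, so its SE does not measure the spread between thawings. Growth above 1 also departs from the constant difference that the dye term assumes. A mixture of a constant and a proportional part stays open. A wrong sign of replicate 3 at 2 h was argued against by a correlation with replicates 1 and 2 of 0.6565 once the difference seen at the other times was removed. Dye and thawing stay open, because the dyes were exchanged only in that replicate.

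At both 48 h and 72 h 10 of 18 antigen presentation genes were higher and 1 was lower. The list calls ended with an estimated correlation (adjusted p = 0.215 and 0.134). Cross-hybridisation among HLA genes could inflate the 6 HLA members that rose at 48 h, which stays open because no probe sequences were used, but it leaves out the 4 risen members outside HLA, namely B2M (0.77), TAP1 (2.36), PSMB8 (1.39) and PSMB9 (1.68). The risen members had a median of 1.754 on the 48 h and 72 h arrays with treated cells in Cy3, but their selection used these arrays as well. A dye bias was argued against by the members chosen on the Cy5 arrays alone, 11 in all, which had a median of 1.517 on these Cy3 arrays. The interferon-stimulated genes outside this list had a median of 0.06557 (bootstrap SE 0.1153) at 48 h. The risen members had 1.626, but they were selected for rising, and all 18 measured members had a median of 0.297, so a general interferon response could contribute and stays open.

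At 72 h 15 of 46 replication-dependent histone genes were higher and 24 of 34 mitotic genes were lower. Both list calls ended with an estimated correlation (adjusted p = 0.558 and 0.327). Of the 15 histone members that rose, 15, 11 and 14 were still called without 72 h replicate 1, 2 and 3, and 11 were called in each of these fits. With the dye term removed the histone medians on the 3 arrays were −0.007, 0.63 and 0.10, and the list call ended without replicate 2 (adjusted p = 0.977). A single array, replicate 2, may therefore contribute to the histone shift, which stays open. The mitotic medians were −0.26, −0.27 and −0.64. Chance co-movement of correlated genes may account for both list calls: 63 of 100 draws without change had a list p as low for the histone genes and 12 of 100 for the mitotic genes. Whether either shift belongs to the treatment stays open.

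Exchanges of treated and untreated on the 3 arrays of a time give 4 splits, too few for 0.05. At 2, 6, 10, 48 and 72 h the real split alone, 1 of 4, reached its count of 1165, 5256, 5438, 6942 and 6559 genes, and the highest other split gave 0, 1, 0, 0 and 47. Of 100 orders of the times within thawings, the real one included, only the real one, 1 of 100, reached 4755 genes for late minus early (highest other 954) and 4277 for the F test (highest other 1833), which argues against chance for these counts.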

How the results depend on the processing

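Testing each probe gave 1771, 7920, 8357, 10939 and 10423 changed probes at 2, 6, 10, 48 and 72 h, 7425 for late minus early and 6424 for the F test, where construction raises the number of units tested. At 2 h scaled arrays gave 3875 genes and array weights 3253 against 1165. The 2 h arrays had the smallest SDs over probes (0.211 to 0.254, against 0.380 to 0.432 at 48 h and 72 h). Scaling to the same spread therefore enlarged their ratios, and the metallothionein median at 2 h went from 0.28 to 0.48. Array weights were 1.277 to 2.744 at 2 h and 0.3919 to 0.7631 at 72 h. Whether these differences account for the whole rise was not tested. Each time fitted alone, which also left out the dye term, gave 2712 genes at 10 h and 2999 at 72 h. Leaving out the dye term alone gave 4565 and 5534 at these times, and 2838 for the F test. Camera with an estimated correlation called 0 lists at 2, 6, 10, 48 and 72 h and for late minus early. Leaving out single arrays or replicates gave 398 to 1453 genes at 2 h, 3655 to 5711 at 6 h, 3389 to 5874 at 10 h, 5111 to 7283 at 48 h, 4213 to 6596 at 72 h, 1998 to 4913 for late minus early and 920 to 5005 for the F test; lists called ran from 7 to 15 of 30. Of 697 named calls 485 held under each alternative run for named genes, which left out the test per probe, and late minus early was not run with each time alone. With the thawing as a block, which separated replicates 1 and 2 only, the counts were 1220, 5232, 5415, 6867, 6594 and 4723, with 4275 for the F test. The block ended or made calls only near the threshold, among them the mitotic list at 48 h (adjusted p = 0.0521), GP5 at 48 h (0.0620) and those given beside the genes. Some signs of named genes reversed without passing when replicates were left out: RPL13 at 10 h ran from −0.058 without replicate 3 to 0.23 without replicate 1, BST2 at 10 h from −0.061 without replicate 3 to 0.63 without replicate 2, GP5 at 48 h from −0.40 without replicate 1 to 0.027 without replicate 3 (0.0093 without 48 h replicate 3), and RAG2 at 72 h from −0.67 without replicate 1 to 0.033 without replicate 3. Among all genes, 2 called at 10 h and 4 called at 72 h passed in the opposite direction without replicate 3 at all times.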

Other observations

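Families of gene symbols were examined after the data were seen, so all tests in this part were chosen after seeing the result. A family held all genes whose symbols begin with the same letters before the first digit, so it can mix genes of unlike function. The 174 families with at least 12 genes were tested at 6 h and 48 h. A 1-sided Fisher exact test compared the share of limma calls in a family with that among all other genes, and p values were adjusted over 348 tests per direction. At 48 h 30 of 50 MRPL genes of the large mitochondrial ribosomal subunit were lower (adjusted p = 6.06e-11), as were 21 of 28 MRPS genes of the small subunit (adjusted p = 1.29e-10). Further families that passed as lower at 48 h, in order of adjusted p, were DDX helicases with 21 of 37 (2.22e-07), EIF genes of translation initiation with 25 of 53 (9.39e-07), TIMM genes of inner membrane translocation with 11 of 14 (5.82e-06), and SNHG host transcripts of small nucleolar RNAs with 11 of 17 (9.67e-05). METTL (12 of 23, 0.000690), POLR (14 of 32, 0.00158), TRMT (9 of 16, 0.00256), EEF and LSM (8 of 13 each, 0.00256), NUP (11 of 25, 0.00641) and WDR (18 of 58, 0.0156) also passed as lower. Examples were MRPL16 (−0.73), MRPS7 (−0.59), TIMM44 (−1.02) and SNHG8 (−0.78). At 6 h 25 MRPL, 18 MRPS, 9 TIMM and 11 SNHG genes were already lower. RBM (17 of 39, adjusted p = 1.64e-06), SRSF (6 of 12, 0.00705) and ALG (6 of 14, 0.0163) passed as lower at 6 h and not at 48 h (0.0903, 0.673 and 0.387). The RPL, RPS and COX symbol families did not pass in either direction at 48 h: RPL had 18 genes higher and 5 lower, RPS 13 and 3, and COX 9 and 2.

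Families that passed as higher at 6 h were MAP with 23 of 46 genes (adjusted p = 0.000724), IFT, of intraflagellar transport, with 12 of 18 (0.00149), CEP with 18 of 37 (0.00373), the syntaxins, STX, with 10 of 15 (0.00496), and RAB with 27 of 70 (0.00618). At 48 h 33 of 70 RAB genes were higher (adjusted p = 0.00149), and so were 35 of 84 ATP genes (adjusted p = 0.00663). IFT genes were higher in 10 cases at 48 h, which did not pass (adjusted p = 0.0971); IFT27 (1.62) and IFT43 (1.03) led at 48 h. Other families of membrane traffic did not pass as higher at 48 h, with 7 VPS genes higher and 7 lower, 6 SEC genes higher and 5 lower, and 7 of 28 SNX genes higher. Annexins were higher in 9 of 15 cases at 48 h and did not pass (adjusted p = 0.0853), with ANXA3 at 2.29. Fisher's test takes genes as independent, but genes of a family are not, and no correlation between them was allowed for. These p values can therefore be too small.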
